A study of Mus musculus with 6 samples.

How the data were processed

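Liver polyA RNA was sequenced in 6 samples of male C57BL/6NJ mice, 3 on a chow diet and 3 on a high fat diet with sugar in the drinking water, each for 54 weeks according to the series text. Per the labels' protocols, frozen liver was homogenised, polyA RNA was isolated with magnetic beads, and libraries were made with a dUTP-based stranded kit, which marks the strand of the RNA. Per the submitters' processing notes, the reads were aligned with STAR to the mouse genome build mm10, with no STAR version named. The counting program, the gene annotation, the strand setting and the rule for reads that fit several genes are not given in the sources used here.

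The values are whole-number counts of reads per gene, as deposited, with no normalisation, 1 table per library and 24982 genes in each. Genes are named by symbol. Each table also has a row for reads outside genes and a row for reads that fitted more than 1 gene. These rows were left out of library sizes and tests. Reads outside genes came to 8.48%, 10.3% and 9.61% of all counts in the table, these rows included, in chow replicates 1, 2 and 3. They came to 8.86%, 10.6% and 7.74% in high fat high sugar replicates 1, 2 and 3. Reads that fitted more than 1 gene came to 0.771%, 0.862% and 0.766% of all counts in chow, and to 0.633%, 0.615% and 0.698% in the high fat high sugar group, with no overlap between the groups. The deposited tables of the 2 diets carry different name stems and the labels give no batch, so a difference in handling between the diets, if there was one, cannot be told apart from the diet.

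Samples were grouped by the diet label and replicates took the number in the title. The labels describe separate samples and do not say in so many words that each came from its own animal, so the p-values measure the spread between these samples. Counts of every pair within a group differed by far more than sampling noise, with a chi-square per gene of at least 23.5, so no library was counted as a copy of another.

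Genes were filtered with filterByExpr of edgeR at its default minimum count of 10, which left 12949 of the 17877 genes with at least 1 count. Libraries were scaled by TMM, and diet was tested with edgeR's quasi-likelihood F test with robust estimation and no covariate (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Benjamini-Hochberg adjustment was over all tested genes and the threshold was an adjusted p of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM, counts scaled to library size, computed here from the deposited counts with TMM-scaled library sizes, as mean ± SD. Principal components used log2 CPM with a prior count of 2.

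Before the data were examined, 38 gene lists were fixed from textbook knowledge of mouse liver, with 696 symbols of which 677 were found in the tables, some through older symbols in the RefSeq gene table. A list was tested against all other tested genes with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 37 lists with a tested member. The 15 mitochondrial genome transcripts had 0 rows in the tables, so that list was not analysed here. Camera with a correlation estimated per list and fry, a rotation test of whether a list moves on balance one way, were alternatives. Counts "adjusted over the list alone" use Benjamini-Hochberg over the tested members of that list.

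The rule for named genes was also fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes past the threshold with a mean count of at least 50 and all 3 libraries of one diet above all 3 of the other, leaving out predicted and unnamed genes, pseudogenes and immunoglobulin or T cell receptor segments. It adds the 3 members with the smallest p of each list, the member with the smallest p in the minority direction, and 29 genes named whatever their value. Other members of the lists are named as examples and were chosen after their values were seen. Some genes that the rule or a list takes are not reported here. Gene spans come from the RefSeq annotation of GRCm38.p6, the assembly that mm10 denotes.

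The main fit, DESeq2, limma-voom and camera were tested on simulated counts drawn from the means, dispersions and sizes of these libraries, with 200 of 12949 genes changed. For 3 chow against 3 high fat high sugar libraries, edgeR recovered 55% of the 100 genes changed 2-fold and 88% of the 100 genes changed 4-fold, with 12 false calls among 155. DESeq2 recovered 68% and 93% with 40 false calls among 201, and limma-voom 54% and 88% with 12 among 154. Camera called both of the changed lists. Genes were simulated independently of each other, so false calls of lists with correlated members were not tested.

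The depth was 16565335 to 20585366 gene counts per library, and 3 counts, taken as the floor, correspond to between 0.1155 and 0.202 CPM. Intervals and floors cover counting error only, since reads are not independent molecules. Alternatives fixed beforehand were no filter, RLE and upper-quartile scaling, DESeq2 (1.42.0), limma-voom, glmTreat against a log2 fold change of 1, a replicate block, thinning to 1 depth, leaving out the 20 most abundant genes, and leaving out each library. Scaling by library size only and limma-voom with sample quality weights were added after the data were seen, as were further scalings, the unfiltered fit and the block for the single lists. Genes with near-identical copies, such as the Mup, Cyp2c, Cyp3a, Serpina1, Sult2a and Ugt families, and antisense or overlapping genes are uncertain, because the counting rule is not given.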

Results

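Liver RNA of male C57BL/6NJ mice was compared between 3 samples labelled as chow-fed and 3 labelled as fed a high fat diet with sugar water (high fat high sugar), each for 54 weeks. The series addresses a diet model in which fatty liver inflammation goes on to liver cancer. The labels do not say whether tumour tissue was part of the sampled liver. Gene counts totalled 20005873, 19246476 and 16565335 in chow replicates 1, 2 and 3, and 18936877, 20585366 and 17647882 in high fat high sugar replicates 1, 2 and 3. Albumin (Alb) was the most abundant gene in every library, with 7.01%, 6.53% and 8.04% of gene counts in chow and 7.27%, 3.05% and 5.11% in the high fat high sugar group. Diet separated the libraries on the first principal component, which held 70.7% of the variance. High fat high sugar replicate 2 stood apart from replicates 1 and 3 of its group: its Pearson correlations across genes with them were 0.961 and 0.957, against 0.982 between replicates 1 and 3. TMM factors were 0.899, 0.945 and 0.897 in chow and 1.02, 1.26 and 1.01 in the high fat high sugar group.

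**Figure D1:**
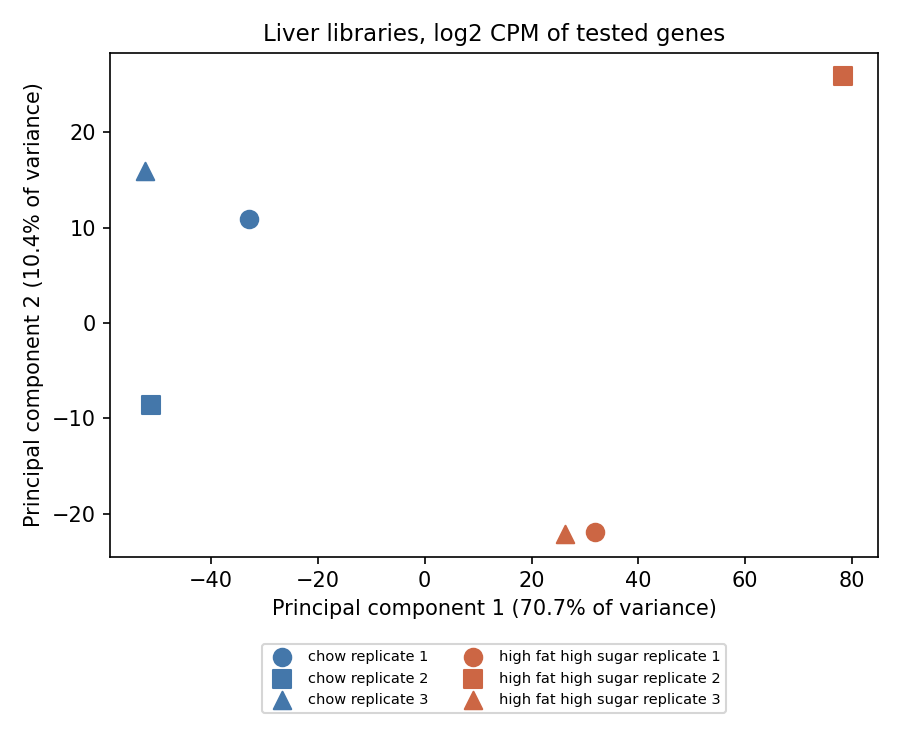
Principal components 1 and 2 of log2 CPM over tested genes, 1 point per library, with colour for diet and shape for replicate number. The axes carry 70.7% and 10.4% of the variance, and high fat high sugar replicate 2 lies at 78.3 on component 1 against 31.9 and 26.2 for replicates 1 and 3.

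After the high fat high sugar diet, members of the matrix (27 of 29), macrophage (16 of 20), MHC class II (9 of 10), bile duct (8 of 14) and cell cycle (12 of 24) lists rose, and members of the drug metabolism (8 of 18), amino acid catabolism (7 of 20) and cholesterol synthesis (4 of 22) lists fell. As lists, 0 of the 37 tested passed camera with an estimated correlation, with a smallest Benjamini-Hochberg adjusted p of 0.201 and 5 at an unadjusted p under 0.05. Of 12949 genes tested, 1428 were higher and 468 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), so that 75.3% of the 1896 calls were rises. The rises were 11.03% and the falls 3.61% of tested genes. A list whose calls lie near these shares is not set apart by its count. In all 1896 the libraries of one diet lay above all 3 of the other, which held for 39.6% of tested genes and is 10% by chance. A rise of at least 1 on the log2 scale was found for 1212 genes and a fall of at least that size for 161. Scaling by library size only, which moved all genes by a median of 0.27 on the log2 scale, gave 1928 higher and 200 lower, 90.6% rises. Without chow replicate 3 the test called 4 genes higher and 2 lower, with a smallest adjusted p of 0.0416 and 1212 genes under an adjusted p of 0.1. Of 99 named genes past the threshold, Cd163, Cyp2c55, Ephb2, Fgf21 and Shc2 passed it without each library in turn and under every alternative run on single genes, which leaves out glmTreat, and the other 94 lost it without chow replicate 3. Lost calls among the 99 came to 32 and 53 without chow replicates 1 and 2, and to 17, 13 and 10 without high fat high sugar replicates 1, 2 and 3. Mup1 and Ier2 lost it without each of the 6 libraries in turn. The counts were 762 and 177 without chow replicate 1, 345 and 113 without chow replicate 2, 1184 and 293 without high fat high sugar replicate 1, and 1664 and 772 without high fat high sugar replicate 3.

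Among genes past the threshold with separated diets and a mean count of at least 50, the largest rise was that of Gpnmb, a glycoprotein of lipid-laden macrophages (chromosome 6, 49036518 to 49058182), from 0.408 ± 0.232 to 86.5 ± 104 CPM (SD, n = 3). Its log2 fold change was 7.70 ± 1.32 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0189) and 5.98 without high fat high sugar replicate 2. Next came Shc2 (6.77 on the log2 scale), the receptor kinase Ephb2 (6.41), the imprinted fetal transcript H19 (6.28), Gipc2 (5.72), the macrophage elastase Mmp12 (5.40), H2-M2 (5.27), Ly6d (5.13), the lipid receptor Trem2 (4.98) and Pls1 (4.85). Counts over the 3 chow libraries came to 4 for Shc2, 6 each for H19 and Gipc2, 9 for H2-M2 and 11 for Ephb2. The size and order of these rises are therefore uncertain. Without high fat high sugar replicate 2 the values were 4.57 for Gipc2, 4.21 for Mmp12, 4.35 for H2-M2 and 3.85 for Trem2. Without chow replicate 1 they were 7.20 for Ephb2, 6.42 for Mmp12, 7.18 for Ly6d, 5.95 for Trem2 and 6.03 for Pls1. The haemoglobin scavenger receptor Cd163 (chromosome 6, 124304636 to 124330529) had the largest fall by the same rule, from 16.7 ± 3.50 to 0.125 ± 0.129 CPM (SD, n = 3), a log2 fold change of -6.97 ± 0.49 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00517) and of -7.82 without high fat high sugar replicate 1. The urinary protein genes Mup12 (-5.18) and Mup1 (-4.69), the imprinted transcript Meg3 (-4.95), Fam19a2 (-4.68), squalene epoxidase Sqle (-3.79), the scavenger receptor Marco (-3.68), Etnppl (-3.43), Susd4 (-3.40) and Cyp2c55 (-3.34) also fell. Over the 3 high fat high sugar libraries Cd163 had 8 counts, Fam19a2 14 and Meg3 16, so the sizes of these falls are uncertain. Mup12 was -4.58 without high fat high sugar replicate 2, Mup1 -3.82 without chow replicate 2 and -4.08 without high fat high sugar replicate 2, Meg3 -4.21 without chow replicate 3 and Sqle -5.39 without high fat high sugar replicate 1. The Mup genes are near-identical copies and their split of reads is uncertain.

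**Figure D2:**
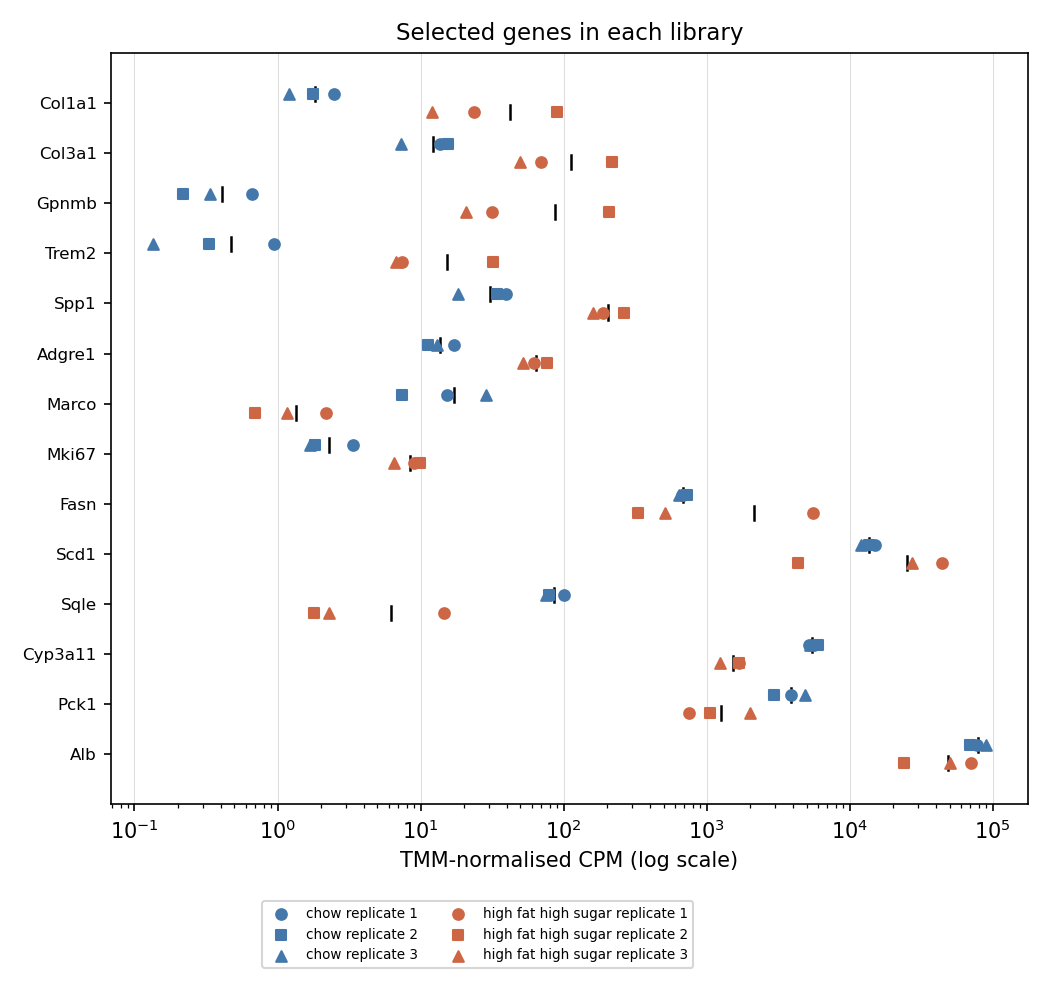
TMM-normalised CPM on a log scale for 14 genes, 1 point per library, with colour for diet, shape for replicate number and a black bar at the group mean. Col1a1 lies between 1.21 and 2.50 CPM in chow and between 12.0 and 90.2 CPM in the high fat high sugar group, while Fasn is at 5570 CPM in high fat high sugar replicate 1 and at 329 and 516 CPM in replicates 2 and 3.

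Fibrillar collagens and other matrix genes rose in 27 of 29 tested members, and in 29 adjusted over the list alone, with a median log2 fold change of 2.25. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), went from 1.82 ± 0.648 to 41.9 ± 42.2 CPM (SD, n = 3), a log2 fold change of 4.51 ± 0.89 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0248). Col3a1, of type III collagen (chromosome 1, 45311538 to 45349706), went from 12.2 ± 4.29 to 112 ± 91.5 CPM (SD, n = 3), 3.20 ± 0.65 (SE) on the log2 scale. Without high fat high sugar replicate 2 these were 3.28 and 2.29. Smaller spreads went with Col14a1 (1.42 ± 0.15), the basement membrane collagen Col4a1 (2.04 ± 0.21) and Col6a2 (2.76 ± 0.29). Timp1, an inhibitor of matrix proteases, was at 0.245 ± 0.367 and 2.60 ± 3.02 CPM (SD, n = 3) and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.115). The list passed camera at a Benjamini-Hochberg adjusted p = 1.41e-26, with adjusted p = 0.345 with an estimated correlation. Stellate cell and myofibroblast markers rose in 11 of 17 members (14 higher and 1 lower adjusted over the list alone), among them Reln (1.15 ± 0.13), the receptor Pdgfrb (2.00 ± 0.27) and Cygb (2.11 ± 0.33). That list had a camera adjusted p = 3.64e-09 (Benjamini-Hochberg), and adjusted p = 0.345 with an estimated correlation. The smooth muscle actin Acta2, the usual mark of activated stellate cells, had a log2 fold change of 1.43 ± 0.51 (SE) and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0982). The median log2 ratio of the matrix list to the chow mean was 2.00, 2.86 and 1.63 in high fat high sugar replicates 1, 2 and 3. With chow replicate 2 left out 14 matrix and 3 stellate cell members rose, and with chow replicate 1 left out 7 stellate cell members did. With chow replicate 3 left out edgeR called 0 in both lists, with 28 and 14 members at an unadjusted p under 0.05.

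Kupffer cell and macrophage markers rose in 16 of 20 members and fell in 2, the same counts as adjusted over the list alone. Adgre1, which encodes F4/80 (chromosome 17, 57358581 to 57483529), went from 13.8 ± 3.03 to 63.7 ± 12.2 CPM (SD, n = 3), 2.21 ± 0.20 (SE) on the log2 scale. The growth factor receptor Csf1r rose by 1.70 ± 0.19, the Kupffer cell lectin Clec4f by 1.02 ± 0.12 and Cd68 by 2.17 ± 0.41. Cd163 and Marco, both scavenger receptors, fell. The Kupffer cell gene Timd4 was at 6.72 ± 2.10 and 4.77 ± 0.762 CPM (SD, n = 3) and did not pass. Camera gave a Benjamini-Hochberg adjusted p = 9.79e-09, and adjusted p = 0.347 with an estimated correlation. Genes of lipid-associated macrophages rose in 9 of 16 members (12 adjusted over the list alone). The smallest p went with Spp1, which encodes osteopontin (2.74 ± 0.32), lipoprotein lipase Lpl (2.94 ± 0.52, and 2.34 without high fat high sugar replicate 2) and Gpnmb. Mmp12 (5.40) and Trem2 (4.98) rose by more than Spp1 and Lpl. This list had a camera adjusted p = 1.84e-08 (Benjamini-Hochberg), and adjusted p = 0.345 with an estimated correlation. MHC class II genes rose in 9 of 10 members (10 adjusted over the list alone), with a median of 2.49 on the log2 scale. H2-Ab1 went up by 2.61 ± 0.51 (1.99 without high fat high sugar replicate 2), H2-DMb1 by 2.51 ± 0.50 and the costimulator Cd86 by 1.77 ± 0.24. The camera adjusted p = 4.26e-08 (Benjamini-Hochberg), and adjusted p = 0.347 with an estimated correlation. The class II median was 1.82 without high fat high sugar replicate 2. Lipid-associated and class II members that rose came to 5 and 4 with no filter on low counts and to 4 and 6 with limma-voom. Macrophage, lipid-associated and class II members that rose came to 6, 2 and 1 without chow replicate 2, and lipid-associated members to 4 without chow replicate 1. Leaving out chow replicate 3, edgeR called 0 higher in the 3 lists, with 18, 11 and 9 members at an unadjusted p under 0.05. Cd163 alone stayed lower in the macrophage list without that library, and 1 member did without high fat high sugar replicate 2.

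Chemokines and cytokines rose in 6 of 16 members (8 higher and 1 lower adjusted over the list alone), with Tgfb1 at 1.36 ± 0.22, Cxcl16 at 1.95 ± 0.34 and Il1a at 1.42 ± 0.26 on the log2 scale. For them the camera adjusted p = 0.00235 (Benjamini-Hochberg), and adjusted p = 0.471 with an estimated correlation. Interferon-stimulated genes rose in 5 of 20 members, also 5 adjusted over the list alone, with the smallest p for Ifit2 (1.83 ± 0.20), Oasl2 (1.80 ± 0.31) and Ifi27l2a (2.03 ± 0.38). The median of that list against the chow mean was 0.56 in chow replicate 1, above the 0.08 of high fat high sugar replicate 1. They had a camera adjusted p = 0.000805 (Benjamini-Hochberg), and adjusted p = 0.471 with an estimated correlation. Among neutrophil markers 1 of 7 rose (4 adjusted over the list alone), the cytokine gene Il1b (1.93 ± 0.51, and 2.62 without chow replicate 1), which macrophages also express, while the neutrophil proteins S100a8 (2.55 ± 0.72) and Csf3r (1.88 ± 0.59) did not pass. S100a8 passed without high fat high sugar replicate 3 (2.84). Both were highest in high fat high sugar replicate 2. S100a8 was at 2.32, 9.35 and 2.46 CPM in replicates 1, 2 and 3 of that group, and Csf3r at 5.22, 15.9 and 4.58 CPM. The camera adjusted p = 0.0199 (Benjamini-Hochberg) became 0.0572 without chow replicate 3 and 0.0684 with library size only, with adjusted p = 0.471 with an estimated correlation. Of 12 tested T, NK and B lymphocyte markers, the NK cell receptor Ncr1 rose (2.51 ± 0.49), and 3 passed adjusted over the list alone. That list missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.0516) and passed it without chow replicate 1 (0.00363), without high fat high sugar replicate 3 (0.0261), with RLE scaling (0.0493) and with no filter on low counts (0.0223). The values not past the threshold were 1.89 ± 0.52 for Klrb1c, which passed without chow replicate 1 (2.59), and 0.97 ± 0.29 for the B cell gene Ms4a1. Chemokine members that rose came to 2, with 1 lower, and interferon-stimulated members to 1 without chow replicate 2. When chow replicate 3 was left out edgeR called 0 in both, with 8 and 5 members at an unadjusted p under 0.05. Neutrophil and lymphocyte rises came to 4 and 2 with DESeq2 and to 2 and 2 without chow replicate 1. Lymphocyte rises also came to 2 without high fat high sugar replicate 3 and with upper-quartile scaling. In the neutrophil list edgeR called 0 without chow replicate 2 or 3 or high fat high sugar replicate 1 or 2, with 3, 2, 5 and 4 members at an unadjusted p under 0.05, and in the lymphocyte list 0 without chow replicate 2 or 3, with 3 and 5.

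Cholangiocyte and ductular markers rose in 8 of 14 members (9 adjusted over the list alone), with Ehf at 2.00 ± 0.38, Epcam at 2.16 ± 0.44 and the keratin Krt19 at 2.14 ± 0.55 on the log2 scale (1.39 for Krt19 without high fat high sugar replicate 2). The chloride channel gene Cftr had 99 counts in the high fat high sugar group and 1 in chow, a ratio of 79.9 with a 95% counting interval of 14.0 to 3186. The ratio was 51.7 without chow replicate 1, 51.4 without chow replicate 2 and 50.7 without high fat high sugar replicate 2. The 1 chow count lay in chow replicate 3, without which the ratio was at least 18.9, taking 3 counts over the chow group as the floor, and Cftr did not pass without chow replicate 2 or 3. The camera adjusted p = 1.74e-05 (Benjamini-Hochberg), and adjusted p = 0.416 with an estimated correlation. Liver endothelial markers rose in 9 of 16 members (11 adjusted over the list alone), with a median of 0.64. Lyve1 went up by 2.36 ± 0.29, Pecam1 by 0.95 ± 0.12 and Plvap by 0.94 ± 0.16. Their camera adjusted p = 1.81e-06 (Benjamini-Hochberg), and adjusted p = 0.345 with an estimated correlation. Cell cycle genes rose in 12 of 24 members (16 adjusted over the list alone), among them the replication helicase genes Mcm6 (from 4.09 ± 0.530 to 11.6 ± 0.732 CPM, SD) and Mcm5 (from 2.09 ± 0.065 to 5.93 ± 0.390 CPM, SD), topoisomerase Top2a (2.57 ± 0.42, and 3.32 without chow replicate 1) and Mki67 (1.87 ± 0.31). Mki67 was at 2.30 ± 0.951 CPM in chow and 8.44 ± 1.75 CPM in the high fat high sugar group (SD, n = 3). Here the camera adjusted p = 9.79e-09 (Benjamini-Hochberg), and adjusted p = 0.345 with an estimated correlation. Liver tumour and oncofetal genes rose in 10 of 16 members (11 adjusted over the list alone), with H19, Scd2 (2.41 ± 0.36) and Spink1 (4.02 ± 0.64, and 5.51 without chow replicate 1 and 3.42 without chow replicate 2). Alpha-fetoprotein, Afp, went from 0.823 ± 0.116 to 3.01 ± 0.670 CPM (SD, n = 3), 1.86 ± 0.30 (SE) on the log2 scale, and Gpc3 was at 0.729 ± 0.412 and 0.572 ± 0.269 CPM and did not pass. The camera adjusted p = 9.79e-09 (Benjamini-Hochberg), and adjusted p = 0.345 with an estimated correlation. Rises in the cholangiocyte, endothelial, cell cycle and tumour lists came to 2, 4, 3 and 4 without chow replicate 2. Cholangiocyte rises came to 3 and endothelial rises to 4 without chow replicate 1, and endothelial rises to 4 and cell cycle rises to 6 without high fat high sugar replicate 1. In the fit that left out chow replicate 3 edgeR called 0 in the 4 lists, with 9, 10, 17 and 11 members at an unadjusted p under 0.05.

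**Figure D3:**
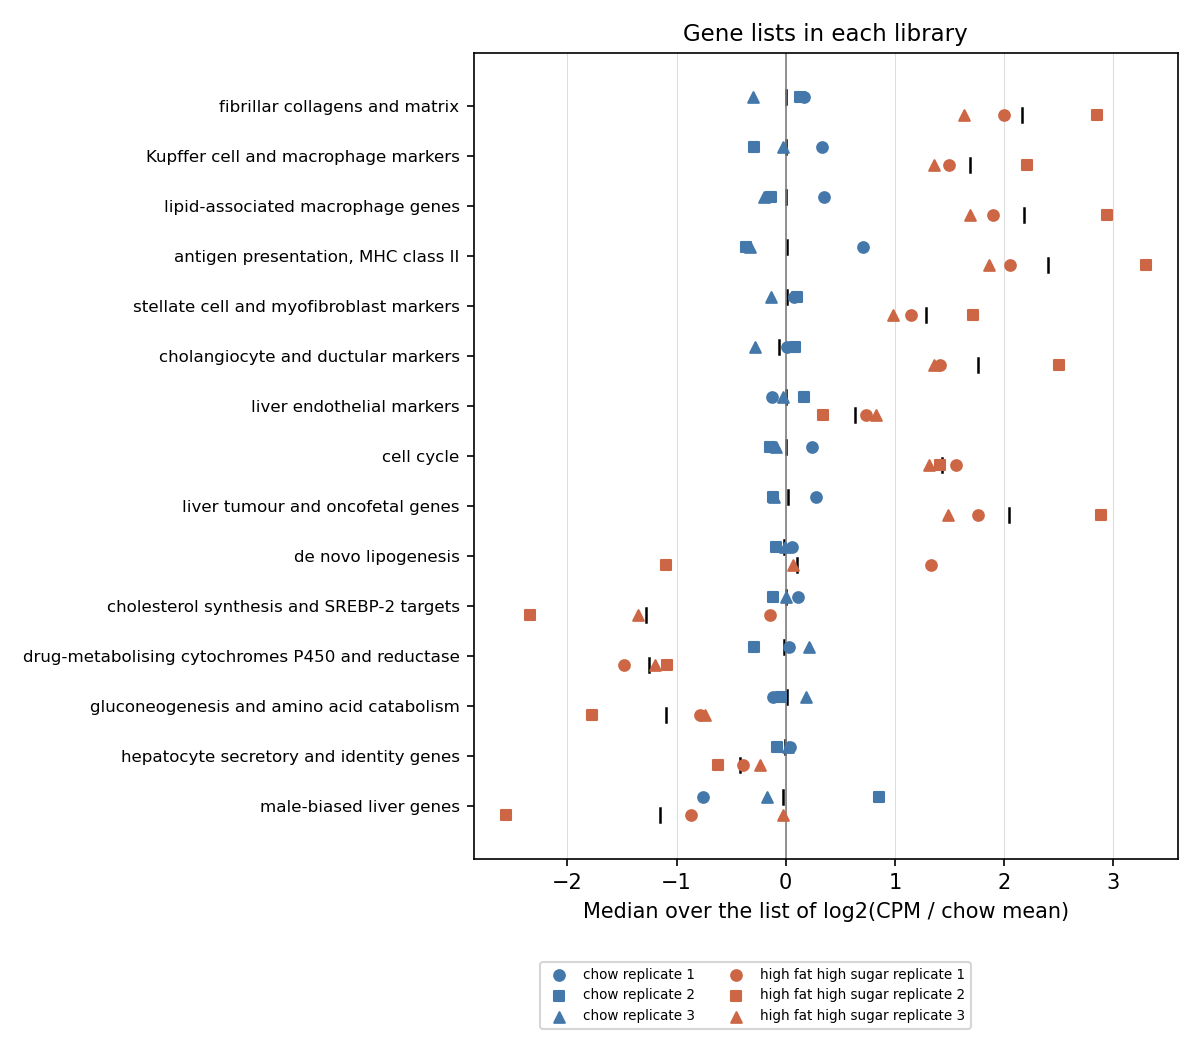
Median over the tested members of 15 gene lists of the log2 ratio of CPM to the chow mean, 1 point per library, with colour for diet, shape for replicate number and a black bar at the mean of the 3 medians. De novo lipogenesis lies at 1.33, -1.097 and 0.06 in high fat high sugar replicates 1, 2 and 3, and the matrix list lies above 1.6 in all 3.

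De novo lipogenesis differed between the high fat high sugar libraries. Fatty acid synthase, Fasn (chromosome 11, 120805958 to 120825166), was at 5570, 329 and 516 CPM in replicates 1, 2 and 3 against 681 ± 49.9 CPM in chow (SD, n = 3). The desaturase Scd1 was at 44024, 4329 and 27352 CPM against 13572 ± 1512 CPM in chow. Neither passed, nor did the regulator Srebf1 (0.73 ± 0.33 on the log2 scale), Pnpla3 (5.01 ± 1.61) or Slc25a1 (-0.78 ± 0.32). Of 20 members 0 passed with edgeR, 0 adjusted over the list alone and 0 with DESeq2, and 2 had an unadjusted p under 0.05. The list median was 0.64 while camera placed the list down and fry up, and it did not pass (camera, Benjamini-Hochberg adjusted p = 0.993). Without high fat high sugar replicate 2 it passed as higher (adjusted p = 0.019 by camera with Benjamini-Hochberg), when 4 members rose, Scd1 (1.40) and Srebf1 (1.05) among them. Without replicate 1 the list passed as lower (0.00957), when 2 members fell and 1 rose, Pnpla3 at 1.85 on the log2 scale. The list median was then -0.29.

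Lipid droplet and uptake genes rose in 3 of 20 members, also 3 adjusted over the list alone: Fabp4 (2.08 ± 0.38), Hilpda (1.07 ± 0.23) and the fatty acid carrier Cd36 (0.90 ± 0.22). Over all tested genes 11.03% rose, a share not far from that of these members. The list did not pass (camera, Benjamini-Hochberg adjusted p = 0.251) and did so without high fat high sugar replicate 2 (0.0346). Cidea, at 20.4 ± 10.6 and 31.8 ± 39.1 CPM (SD, n = 3), and Cidec, at 40.8 ± 14.8 and 120 ± 92.0 CPM, did not pass. Among PPAR-alpha targets and oxidation genes 1 of 22 rose, also 1 adjusted over the list alone: the hormone Fgf21 (chromosome 7, 45613890 to 45615490), from 0.477 ± 0.182 to 10.6 ± 3.26 CPM (SD, n = 3), 4.44 ± 0.36 (SE) on the log2 scale. The list median was -0.12 while camera placed it up, and it did not pass (Benjamini-Hochberg adjusted p = 0.993), with Crat at 0.68 ± 0.24 and Pdk4 at 1.08 ± 0.40 not past the threshold. Crat passed without high fat high sugar replicate 2 (0.87). DESeq2 called 5 lipid droplet and 3 oxidation genes higher, and library size only gave 5 and 4. Oxidation rises came to 2 without high fat high sugar replicate 2, and 1 lipid droplet gene fell without high fat high sugar replicate 3. Rises of lipid droplet members came to 1 without chow replicate 2, and edgeR called 0 without chow replicate 1 or 3, with 5 and 4 members at an unadjusted p under 0.05.

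Cholesterol synthesis genes had negative log2 fold changes in all 22 members and fell past the threshold in 4 (8 adjusted over the list alone), with a median of -0.88. Sqle (chromosome 15, 59315092 to 59331193) went from 85.5 ± 13.7 to 6.22 ± 7.23 CPM (SD, n = 3), and Mvk and Fdft1 fell by 1.26 ± 0.24 and 1.12 ± 0.24 on the log2 scale. The list median lay at -0.14, -2.34 and -1.35 in high fat high sugar replicates 1, 2 and 3. Camera gave a Benjamini-Hochberg adjusted p = 7.25e-08, and adjusted p = 0.471 with an estimated correlation. Cholesterol efflux and LXR targets rose in 4 of 12 members (5 higher and 1 lower adjusted over the list alone): the sterol exporters Abca1 (0.61 ± 0.13) and Abcg1 (2.03 ± 0.43, and 1.38 without high fat high sugar replicate 2), Mylip (1.17 ± 0.26) and Abcg5 (0.81). That list did not pass (camera, Benjamini-Hochberg adjusted p = 0.212). Bile acid genes fell in 1 of 22 members, also 1 adjusted over the list alone, the transporter Slco1a4 (-1.71 ± 0.33), with Baat (-0.49 ± 0.15) and Slc27a5 (-1.11 ± 0.32) not past the threshold, which Slc27a5 passed without high fat high sugar replicate 2 (-0.81). Over all tested genes 3.61% fell, a share near that of the bile acid list. The bile acid list had a camera adjusted p = 0.00235 (Benjamini-Hochberg), and adjusted p = 0.347 with an estimated correlation. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 387 ± 165 and 314 ± 75.4 CPM (SD, n = 3) and Cyp8b1 at 427 ± 219 and 254 ± 170 CPM, and neither passed. Falls among bile acid genes came to 5 with DESeq2 and 4 with sample quality weights, and 7 members had an unadjusted p under 0.05. They came to 3 without high fat high sugar replicate 2 and 2 without high fat high sugar replicate 3, and edgeR called 0 without chow replicate 1 or 3, with 7 and 2 at an unadjusted p under 0.05. Cholesterol synthesis had 9 falls with DESeq2 and 2 with no filter on low counts. It had 16 falls and a median of -1.81 without high fat high sugar replicate 1, 2 falls without high fat high sugar replicate 3 and 1 without chow replicate 1. For it edgeR called 0 without chow replicate 2 or 3, with 10 and 8 members at an unadjusted p under 0.05. Efflux genes had 2 rises with limma-voom and without high fat high sugar replicate 1, 1 fell without high fat high sugar replicate 3, and edgeR called 0 without chow replicate 1, 2 or 3, with 5, 7 and 5 members at an unadjusted p under 0.05.

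Drug-metabolising cytochromes P450 fell in 8 of 18 members (12 adjusted over the list alone), with a median of -1.14. Cyp3a11 (chromosome 5, 145854607 to 145879854) went from 5500 ± 454 to 1542 ± 259 CPM (SD, n = 3), -1.83 ± 0.23 (SE) on the log2 scale. Cyp2c37 fell by 2.13 ± 0.25 and Cyp2b10 by 4.43 ± 0.60 (5.78 without high fat high sugar replicate 1 for the latter). The list passed camera at a Benjamini-Hochberg adjusted p = 3.74e-14, and adjusted p = 0.201 with an estimated correlation. Gluconeogenesis and amino acid catabolism fell in 7 of 20 members (11 adjusted over the list alone): Hal, which degrades histidine (-1.91 ± 0.28), Agxt (-1.64 ± 0.36) and Gls2 (-1.65 ± 0.38) had the smallest p. Pck1, the rate-limiting enzyme of gluconeogenesis, went from 3890 ± 950 to 1270 ± 648 CPM (SD, n = 3). The camera adjusted p = 2.14e-08 (Benjamini-Hochberg), and adjusted p = 0.347 with an estimated correlation. Glycolysis and fructose genes rose in 4 of 18 members (5 adjusted over the list alone): Pkm (1.87 ± 0.25), Hk1 (1.36 ± 0.19), Hk3 (1.77 ± 0.40) and Aldoa (0.58), isoforms that cells other than hepatocytes use. The median of that list against the chow mean was -0.02 in high fat high sugar replicate 2, under the 0.02 and 0.03 of chow replicates 1 and 3. Their camera adjusted p = 0.0129 (Benjamini-Hochberg) became 0.0657 without high fat high sugar replicate 1, with adjusted p = 0.347 with an estimated correlation. Hepatocyte secretory and identity genes had 1 rise, Apoa4 (3.21 ± 0.39), and 1 fall, the anticoagulant Proc (-0.58 ± 0.15), among 22, the same counts as adjusted over the list alone, with a median of -0.40. Of these 22, 20 had negative log2 fold changes and 10 an unadjusted p under 0.05, and 9 fell with DESeq2 and 8 with sample quality weights. They had a camera adjusted p = 0.00483 (Benjamini-Hochberg), and adjusted p = 0.471 with an estimated correlation. Alb was at 78930 ± 10319 and 48534 ± 23510 CPM (SD, n = 3), and transthyretin, Ttr, at 6393 ± 122 and 3508 ± 818 CPM. Neither passed, and Ttr did without high fat high sugar replicate 2 (-0.69) or 3 (-1.05 on the log2 scale). Falls among the cytochromes came to 13 with sample quality weights, those of amino acid catabolism to 12 with DESeq2 and rises of glycolysis to 8 with library size only. Falls among the cytochromes came to 5 without chow replicate 1 and to 1 without chow replicate 3, and those of amino acid catabolism to 1 without chow replicate 1 or 2. Glycolysis had 2 rises without chow replicate 2. Amino acid catabolism and glycolysis had 0 edgeR calls without chow replicate 3, with 8 and 4 members at an unadjusted p under 0.05. Hepatocyte falls came to 2 and 3 without high fat high sugar replicates 2 and 3. For them edgeR called 0 without chow replicate 1, 2 or 3 or high fat high sugar replicate 1, with 5, 9, 5 and 8 members at an unadjusted p under 0.05, and Apoa4 did not pass without chow replicate 3.

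Sphingolipid and S1P genes went both ways, with 5 of 32 higher and 3 lower (7 and 3 adjusted over the list alone) and no shift as a list (camera, Benjamini-Hochberg adjusted p = 0.999). Sptlc2, a subunit of serine palmitoyltransferase, rose by 0.77 ± 0.11, and its relative Sptlc3 had 3 counts in the high fat high sugar group and 85 in chow, a ratio of 0.0285 with a 95% counting interval of 0.00576 to 0.0861. Its ratio was 0.0483 without high fat high sugar replicate 2 and 0.0132 without high fat high sugar replicate 3. The receptor S1pr2 (chromosome 9, 20965952 to 20976793) went from 7.22 ± 0.597 to 14.8 ± 2.80 CPM (SD, n = 3), and the kinase Sphk1 from 0.152 ± 0.078 to 1.09 ± 0.738 CPM, a log2 fold change of 2.79 ± 0.68 and of 2.07 without high fat high sugar replicate 2. Sphk2 was at 51.9 ± 11.5 and 38.6 ± 5.93 CPM and did not pass. Higher and lower members came to 3 and 1 without chow replicate 1 and to 1 and 1 without chow replicate 2, and 3 were higher without high fat high sugar replicate 2. For this list edgeR called 0 without chow replicate 3, with 12 members at an unadjusted p under 0.05.

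Periportal genes fell in 6 of 17 members (11 adjusted over the list alone), with the smallest p for Hal, Gls2 and Etnppl (-3.43 ± 0.49). This list, which shares its called members Hal, Gls2, Pck1 and Asl with amino acid catabolism, had a camera adjusted p = 2.14e-08 (Benjamini-Hochberg), and adjusted p = 0.347 with an estimated correlation. Of 17 pericentral genes 0 passed with edgeR and 0 adjusted over the list alone, 5 had an unadjusted p under 0.05 and DESeq2 called 4. That list did not pass (camera, Benjamini-Hochberg adjusted p = 0.0944), with Cyp1a2 at -0.96 ± 0.33 (-1.44 and passing without high fat high sugar replicate 2), Lhpp at -1.28 ± 0.44 (-1.79 and passing without high fat high sugar replicate 3) and Cyp27a1 at -0.63 ± 0.24, and it passed as lower without chow replicate 2 (0.0233), chow replicate 3 (0.0464) or high fat high sugar replicate 3 (0.0199), with no filter on low counts (0.0388) and with library size only (0.0247). Male-biased liver genes fell in 2 of 22 members, also 2 adjusted over the list alone, Susd4 and Nat8 (-1.34 ± 0.31), while Bcl6 (-2.33 ± 0.60) did not pass, and did without chow replicate 1 (-2.80). Of the 22, 6 had an unadjusted p under 0.05 and DESeq2 called 6 lower. For them the camera adjusted p = 0.000261 (Benjamini-Hochberg), and adjusted p = 0.471 with an estimated correlation. Their median against the chow mean was -0.86, -2.56 and -0.02 in high fat high sugar replicates 1, 2 and 3, and -0.76, 0.85 and -0.17 in the chow libraries. Among female-biased genes 1 of 19 fell, also 1 adjusted over the list alone, Cyp2b10, and Sult1e1 (4.14 ± 1.17) and Hao2 (-2.16 ± 0.68) did not pass. Sult1e1 was 2.74 without high fat high sugar replicate 1, and it passed without high fat high sugar replicate 3 (4.59). The list median was 0.05 while camera placed it down, without passing (Benjamini-Hochberg adjusted p = 0.651). Circadian genes fell in 2 of 17 members (4 adjusted over the list alone), Cry2 (-0.52 ± 0.09) and Ciart (-1.23 ± 0.26), and Tef (-0.44 ± 0.12) did not pass. DESeq2 and sample quality weights each called 4 lower. The camera adjusted p = 0.00908 (Benjamini-Hochberg), and adjusted p = 0.345 with an estimated correlation. Periportal falls came to 11 with DESeq2 and to 2 without chow replicate 1 or 2, and edgeR called 0 without chow replicate 3, with 8 members at an unadjusted p under 0.05. Male-biased falls came to 1 without chow replicate 2 or high fat high sugar replicate 1, and edgeR called 0 without chow replicate 3, with 6 at an unadjusted p under 0.05. Circadian falls came to 1 without high fat high sugar replicate 1, and edgeR called 0 without chow replicate 2 or 3, with 9 and 5 at an unadjusted p under 0.05. Among pericentral genes 1 fell without high fat high sugar replicate 2 and 2 without high fat high sugar replicate 3. The female-biased median was 0.88 without chow replicate 1 and 0.75 without chow replicate 3. In that list 2 members rose without high fat high sugar replicate 1 or 3, and edgeR called 0 without chow replicate 3, with 3 at an unadjusted p under 0.05.

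Stress lists did not pass camera. Phlda3 (1.53 ± 0.36) rose alone among 15 p53 targets, also 1 adjusted over the list alone, with Cdkn1a, which encodes p21, at 2.66 ± 1.54 and 9.54 ± 5.80 CPM (SD, n = 3) and Aen at 0.39 ± 0.13 on the log2 scale not past the threshold (camera, Benjamini-Hochberg adjusted p = 0.212). In the unfolded protein and integrated stress response, the transcription factor Atf3 rose (3.06 ± 0.65, and 2.27 without high fat high sugar replicate 2) and asparagine synthetase Asns (-1.95 ± 0.40) and Herpud1 (-0.81 ± 0.22) fell among 19, the same counts as adjusted over the list alone. The median was 0.00 while camera placed the list down (Benjamini-Hochberg adjusted p = 0.667). Of 16 NRF2 targets G6pdx rose (1.71 ± 0.25) and Gsta4 (-1.32 ± 0.28) and Ugdh (-0.78 ± 0.18) fell, again the same adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.993). The NRF2 list median against the chow mean was -0.49, 0.76 and -0.24 in high fat high sugar replicates 1, 2 and 3. Of 20 acute phase genes 0 passed with edgeR and 0 adjusted over the list alone, 1 had an unadjusted p under 0.05 and DESeq2 called 1 (camera, Benjamini-Hochberg adjusted p = 0.668). Without chow replicate 1 that list passed (0.00363) and 3 members rose. Values were 3.05 ± 1.27 for Lcn2, which was 5.66 and passed without chow replicate 1, -0.67 ± 0.25 for Saa4 and 0.54 ± 0.24 for Cp. Among 15 immediate early genes Jun rose (1.01 ± 0.24) and Ier2 fell (-0.44 ± 0.12), with 4 higher and 2 lower adjusted over the list alone, and Egr2 (3.24 ± 0.94) did not pass (camera, Benjamini-Hochberg adjusted p = 0.601). Egr2 was 1.77 without high fat high sugar replicate 2, and it passed without high fat high sugar replicate 1 (3.66) or 3 (3.58). DESeq2 called 2 p53 targets higher and 1 lower, and 4 immediate early genes higher and 2 lower. With upper-quartile scaling 2 p53 targets rose.

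Leaving out 1 library changed most calls in the stress lists. Phlda3 passed without high fat high sugar replicate 2, when 1 other p53 target fell, and 2 p53 targets rose without high fat high sugar replicate 3. In that list edgeR called 0 without chow replicate 1, 2 or 3 or high fat high sugar replicate 1, with 3, 6, 2 and 4 members at an unadjusted p under 0.05. Falls in the unfolded protein list came to 1 without chow replicate 1 or high fat high sugar replicate 3. For falls there edgeR called 0 without chow replicate 2 or 3 or high fat high sugar replicate 1, with 4, 3 and 4 members at an unadjusted p under 0.05, and Atf3 did not pass without chow replicate 2 or 3. NRF2 targets had 2 rises and 3 falls without high fat high sugar replicate 2 and 1 fall without high fat high sugar replicate 3. For falls of NRF2 targets edgeR called 0 without chow replicate 1, 2 or 3 or high fat high sugar replicate 1, with 4, 4, 3 and 7 members at an unadjusted p under 0.05, and 0 with library size only, with 4. G6pdx did not pass without chow replicate 3. Of the immediate early genes 2 rose without high fat high sugar replicate 1, 2 or 3, and 1 fell without replicate 2 of these alone. When chow replicate 1, 2 or 3 was left out edgeR called 0 of them, with 8, 6 and 6 at an unadjusted p under 0.05.

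Markers of blood and neighbouring tissues had few tested members. Among 4 erythroid genes Alas2 fell (-1.56 ± 0.37), also 1 adjusted over the list alone. That list missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.0607) and passed as lower without chow replicate 2 (0.00246), chow replicate 3 (0.0276), high fat high sugar replicate 2 (0.0346) or high fat high sugar replicate 3 (0.00181), with no filter on low counts (0.0154) and with library size only (0.00366). Of 6 adipose genes Pck1, which liver also expresses, fell, also 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0927). Car3 (-1.72 ± 0.56) did not pass in the main fit and did without high fat high sugar replicate 2 (-1.29). DESeq2 called 2 adipose genes lower. The adipose list passed as lower without high fat high sugar replicate 3 (0.00125), with no filter on low counts (0.0311) and with library size only (0.00556). Cfd, an adipocyte protease, was at 0.465, 0.154 and 37.0 CPM in high fat high sugar replicates 1, 2 and 3 against 2.94 ± 1.77 CPM in chow (SD, n = 3). Its log2 fold change was 2.06 ± 1.74 and did not pass, and without high fat high sugar replicate 3 it was -3.31 and passed. Cela1 was the 1 tested gene of the exocrine pancreas list and fell (-0.96 ± 0.25), also adjusted over the list alone, and the list passed without chow replicate 1 alone (camera, Benjamini-Hochberg adjusted p = 0.149, and 0.0253 without it). Nnt, a mitochondrial gene in which the related C57BL/6J strain carries a deletion, was at 183 ± 19.2 and 198 ± 14.6 CPM (SD, n = 3) and did not pass. Erythroid and adipose falls came to 2 and 3 without high fat high sugar replicate 3. Without chow replicate 1, 2 or 3 or high fat high sugar replicate 1, edgeR called 0 erythroid genes, with 1, 2, 1 and 1 at an unadjusted p under 0.05, and 0 adipose genes, with 2, 1, 2 and 2. Cela1 passed without chow replicate 1 and in no other fit to 5 libraries.

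By camera at the preset correlation 13 lists were higher and 8 lower, and 16 did not pass. Fry called 6 higher and 2 lower. Other splits of the 6 libraries into 3 and 3 gave up to 18 lists in one direction at the preset correlation, more than the 13 of the diet split. Each of those splits mixes the diets unevenly and keeps part of the diet difference. They therefore do not show how many lists would pass without a diet difference.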

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

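The tests of Y-linked genes, of the female-biased list, of the male pattern, of replicate 2 standing apart and of the rise of non-hepatocyte lists were chosen only after the result was seen, while the tests of further female-specific genes and of other splits were written before. Xist, the RNA of the inactive X chromosome, belongs to no comparison of diets, and in these livers labelled male it stood above its level in the chow samples. It was at 5.7 CPM in high fat high sugar replicate 2 (148 counts) and at 4.13 CPM in replicate 3 (74 counts), against 0.103 CPM in replicate 1 and between 0.055 and 0.389 CPM in chow.

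Cyp3a41a, a transcript of female liver chosen after its values were seen, had 46 and 26 counts in high fat high sugar replicates 2 and 3 and at most 1 in each other library. Of 26 female-biased list members with at least 3 counts 8 were highest in both, 7 of them among the 9 under 1 CPM elsewhere, a choice that favours the pair. List medians against the chow mean were 0.787 and 0.669, between the 0.619 and 0.912 of chow replicates 1 and 3. Of the 8 members highest in both, Cux2 and Cyp2a4 were at 8.93 and 281 CPM in replicate 2. In replicate 3 they were at 0.559 and 35.8 CPM, close to the 0.445 and 30.8 CPM of chow replicate 1. Female animals are argued against: the mean CPM of Ddx3y, Uty, Kdm5d and Eif2s3y in the pair was 0.866 of the chow mean. It was 0.792 in replicate 2, the lowest of the 6 libraries, and 0.939 in replicate 3, with the others at 0.941 to 1.043. Female liver RNA or reads mixed into these libraries may explain the pattern and stays open. Of 8 further female-specific genes with at least 3 counts, 4 were highest in both, Sult2a3, Sult2a4, Sult2a5 and Sult2a6. The prediction needed more than 4 and was not met, and chance gives 6.67% of them. Slc22a29, Cyp2c39, Ntrk2 and Cyp2g1 were not highest in both, and lay between 1.65 and 19.077 CPM in the chow libraries. A small share of female RNA need not lift such genes above every other library, so this test cannot decide the question. The 4 Sult2a genes are near-identical copies that can share reads, and their counts were low. Sult2a3 had 7 and 10 counts in high fat high sugar replicates 2 and 3, Sult2a4 5 and 2, Sult2a5 11 and 4 and Sult2a6 6 and 6. The 2 counts of Sult2a4 in replicate 3 lay under the floor of 3 counts. Sult2a5 had 3 counts in chow replicate 1, close to its 4 in replicate 3.

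A loss of the male pattern of hepatocyte expression was weighed for each of the pair. In replicate 3 the median log2 ratio of the 22 male-biased genes to the chow mean lay 0.843 above that in replicate 1, where Xist is not raised (95% bootstrap interval over genes 0.037 to 1.108). The prediction of a loss, a median below that of replicate 1, was thus not met. These intervals measure spread over genes between single libraries, not between samples. The same median was -0.759, 0.851 and -0.174 in the chow libraries, so the difference cannot decide the question in replicate 3. A paired form of this test was run first and replaced because the written prediction named the difference of medians. It gave 0.108 with an interval of -0.292 to 0.796, which spans 0, so the result also rests on the form of the test. In replicate 2 the difference was -1.697 (-3.417 to -1.128), and -2.282 (-3.164 to -1.548) in the paired form. There the 17 tested female-biased genes that reached 1 CPM in chow or in replicate 1 had a median of 0.276 with an interval of -0.349 to 1.285, so a loss of the male pattern in replicate 2 may hold and stays open. Slco1a1, a male-biased transporter gene, was at 0.885 CPM in replicate 2 against 114 and 323 CPM in replicates 1 and 3, and the female-biased Cyp2a4 was at 281 CPM against at most 35.8 CPM there.

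High fat high sugar replicate 2 stood apart in its group. Sequencing depth is argued against, since with all libraries thinned to 1 depth its mean distance to replicates 1 and 3 was 1.51 times the distance between them. Female RNA at a level like that in replicate 3 is argued against as the whole cause, because replicate 2 lay 1.47 times as far from replicate 1 as replicate 3 did. A lower share of hepatocyte RNA with the other cell types in constant proportion would move the matrix and endothelial medians alike. The matrix median exceeded the endothelial median by 1.304 on the log2 scale (95% bootstrap interval over genes 0.85 to 1.771). Genes were resampled as if independent, while the estimated correlation in the matrix list was 0.758, so the interval is likely too narrow. It does not measure spread between samples. The size of the gap argues against this explanation, in 1 library only. More advanced disease, sampled tumour tissue and handling were not tested and stay open.

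The rise of matrix, macrophage and other non-hepatocyte lists was weighed against scaling and cell composition. Under RLE, upper-quartile and library-size scaling at least 27 matrix genes were higher, as many as with TMM. These scalings moved all genes by medians of -0.0021, 0.088 and 0.269 on the log2 scale, so hardly down or up. They could scarcely have lowered the count, so this check cannot decide whether scaling plays a part. A lower share of hepatocyte RNA alone, with other cells in constant proportion, is argued against by a gap between the matrix and endothelial medians. The gap was 1.611 (95% bootstrap interval over genes 1.177 to 2.389, likely too narrow for the same reason). Matrix medians against the chow mean were 1.998, 2.856 and 1.633 in high fat high sugar replicates 1, 2 and 3. Endothelial medians were 0.735, 0.343 and 0.824. A change in the number or the state of particular cell types may underlie the rise, and these tests do not separate the 2. A difference in handling between the diets cannot be told apart from diet, because the labels give no batch.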

How the results depend on the processing

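The tests with library size only and limma-voom with sample quality weights, and those of single lists under other scalings, no filter and the replicate block, were chosen only after the result was seen. No gene called with edgeR and TMM changed sign under any of the 17 alternatives to that fit. In all 1896 of these genes the diets were fully separated, and every alternative reuses the same libraries. A kept sign was thus nearly fixed in advance and is no measure of how stable the calls were. Genes lower, 468 with TMM, came to 974 with DESeq2, 849 with sample quality weights and 200 with library size only. Against a log2 fold change of 1, glmTreat called 41 higher and 9 lower, a stricter hypothesis by construction, with at most 2 members of a list in either direction. The other fits to all 6 libraries, apart from the replicate block, gave 997 to 1928 genes higher.

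Leaving out 1 library gave 4 to 1664 genes higher and 2 to 772 lower. The low end came without chow replicate 3, where 1212 genes had an adjusted p under 0.1 (edgeR quasi-likelihood, Benjamini-Hochberg) and 3203 an unadjusted p under 0.05. Log2 fold changes there correlated at 0.989 across genes with those of all 6 libraries. Each such fit shares 5 libraries with the main fit, so this correlation, 0.966 to 0.989 over these fits, is high by construction. The other fits to 5 libraries called 939 and 458 genes without chow replicates 1 and 2, and 1477 to 2436 without a high fat high sugar library. Calls thus dropped most when a chow library was left out, and the cause was not tested. Of 99 named genes past the threshold, 27 moved by over 1.5 times without some library.

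Same-numbered samples did not deviate together (correlations across genes of -0.253, -0.166 and 0.029), and no sample correlated best with its own number. The replicate block gave 961 genes higher and 282 lower, and 13 lists higher and 11 lower. Pericentral, erythroid and adipose lists passed with it. Members that rose with it came to 10 of the macrophage, 6 of the lipid-associated and 1 of the class II list, 3 of sphingolipids, 2 of glycolysis and 1 each of efflux and lipid droplet genes, and those that fell to 4 of amino acid catabolism. For hepatocyte genes edgeR called 0 lower with it, where 9 had an unadjusted p under 0.05 and DESeq2 without it called 9 lower.

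Lists were 13 higher and 8 lower with camera at the preset correlation, 0 and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and 6 and 2 with fry. Leaving out 1 library gave 12 to 15 higher and 9 to 11 lower. De novo lipogenesis, placed down by camera with all libraries and not passing, passed as higher without high fat high sugar replicate 2 and as lower without replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.019 and 0.00957), and the adjusted p was 0.866 to 0.978 without each of the other 4 libraries in turn. Cfd ranged from -3.3051 without high fat high sugar replicate 3 to 2.6476 without replicate 2. Where no construction is named above, the cause was not tested. At this depth, genes with under 3 counts in a library lie under the floor.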

Other observations

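The tests of gene families were chosen only after the result was seen, and those of other splits were planned. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For genes the diet split gave 1428 higher and 468 lower, and the highest of the other splits was 0 in either direction, so 1 split of 10 gave as many. For lists the diet split gave 13 higher, reached by 4 splits, and 8 lower, reached by 8, and the highest of the others was 18. Every other split mixes the diets unevenly, so part of the diet difference stays between its groups and part within them. Neither the 0 genes nor the 18 lists thus show what a split without a diet difference would give.

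Among 26 gene families tested with Fisher's exact test and Benjamini-Hochberg adjustment, C-type lectins held 13 rises of 20 (adjusted p = 6.5e-07) and toll-like receptors 9 of 12 (adjusted p = 9.88e-06). Cyp2 genes held 9 falls of 35 (adjusted p = 5.15e-05) and Ugt genes 6 of 17 (adjusted p = 0.000247). Members of a family can share reads and are not independent.

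The leptin receptor gene Lepr rose by 4.49 ± 0.42 on the log2 scale (SE), and Meg3 (-4.95) and its neighbour Rian (-4.25) fell. These genes other than Meg3 were chosen after their values were seen. The argininosuccinate synthase gene Ass1 was at 0.99 to 1.95 CPM in chow, and Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were listed at 0 in all 6 libraries, levels that depend on a counting rule that is not given in the sources used here.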
